A study of Mus musculus with 6 samples.

How the data were processed

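RNA was sequenced from Thy1+HE- cells sorted from the hearts of C57BL/6 mice 7 days after a sham operation (3 libraries) or after transaortic constriction (TAC, 3 libraries), a surgical narrowing of the aorta that loads the left ventricle with pressure. Thy1 is a surface protein carried by many cardiac fibroblasts. The labels do not spell out HE, and it is used here as they write it. They do not say whether each library came from 1 animal or from a pool, so the p-values measure only the spread between these samples, which may be partly technical.

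Each library had 1 deposited report with 26459 gene rows. The read counts per gene were made with NextGENe 2.3.3, per the file headers, and the submitters' processing notes name the mouse build mm10 and Partek 6.6 without giving their roles. The same deposited reports hold RPKM values that the authors computed from these counts and the row's gene length. How reads with several matches or reads over overlapping genes were treated is not given in the sources used here, and the library kit does not mark strand, so members of near-identical families and overlapping or antisense genes share an uncertain part of their reads. The file headers give 6831001 to 11162756 reads in all and 6027855 to 9736461 matched reads per library. These are fewer reads than the labels state per sample, and the difference is not explained in the sources used here. The counts on gene rows summed to 2056097, 1909337 and 2017868 in sham replicates 1, 2 and 3 and to 3400937, 4207312 and 3351479 in TAC replicates 1, 2 and 3. A floor of 3 counts corresponds to between 0.713 and 1.57 CPM (counts scaled to a common library sum) in a single library, and covers counting error only.

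The counts as deposited were analysed in R 4.3.3. Rows with the same symbol were summed, which left 26458 symbols. Genes were kept by filterByExpr of edgeR 4.0.16, which left 12612 genes, and libraries were scaled by TMM. The groups were compared with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values are scaled by the TMM library sizes. Current symbols and GRCm38 coordinates came from the RefSeq table of GRCm38.p6, the assembly that mm10 names: 14654 symbols were current and 4956 matched through a unique synonym.

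Before the data were examined, the groups, the test, the alternatives, the rule for named genes and 36 gene lists were fixed. The named genes were the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the groups, 28 genes tied to the study's subject, and from each list the 4 called members with the smallest adjusted p, or where none was called the 2 with the highest CPM. That rule left out rows with no symbol, and rows whose symbol is only a number after LOC or EG were counted as such, a reading made after the files were seen. Lists with at least 5 tested members were tested with camera of limma 3.58.1, which asks whether a list's members differ more than other genes, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The values of cell type markers, summed per library, were compared by a two-sided exact permutation test, for which 3 against 3 libraries cannot go below p = 0.1.

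The steps were tested on simulated data built from the sham means and the real library sizes. With 12464 genes kept, the test recovered 75 of 100 genes changed 2-fold and 95 of 100 changed 4-fold, and called 7 unchanged genes. The simulated genes varied independently, so this does not test camera under correlated genes. All of them also had the same spread beyond counting noise, and the changed genes were not drawn from the lowest ones. The recovery and the false calls may therefore differ in the real libraries. Alternatives covered other scalings, filters and tests (DESeq2 1.42.0, limma voom, limma on log2 of the deposited RPKM with pseudocounts of 1 and 0.1), a robust fit, a replicate block, and leaving out each library. Thinning to the smallest library, removal of length or GC trends, omission of numbered loci and omission of both libraries numbered 3 were added after seeing the data. GC content came from GENCODE transcripts and covered 81.3% of the tested genes. Plots were drawn with matplotlib 3.10.9.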

Results

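The study asked about proliferation and activation of cardiac fibroblasts under pressure overload, and these samples address it by comparing 1 sorted population, Thy1+HE- heart cells, between TAC and sham operation at 7 days. There were 3 libraries per group. Counts on genes ranged from 1909337 to 2056097 per library in sham and from 3351479 to 4207312 in TAC, so low genes were measured less precisely in sham. The first principal component of log2 CPM held 55.7% of the variance and separated the groups. Pairs of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of 3.21 to 14.5, which does not tell separate animals from separate preparations of 1 RNA.

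After TAC, most called genes for collagens, matricellular proteins and mitosis were higher, and most called complement and resting-fibroblast genes were lower. With an estimated correlation between genes, only the matricellular list among these 4 kept a camera adjusted p under 0.05, and the lists of proteoglycans and matrix proteases were not called with either correlation. The fry test of limma asks whether a list's members differ between the groups, without comparing them with other genes. All 4 passed it, with fry adjusted p of 0.000124 (collagens), 0.000124 (matricellular), 0.00230 (mitosis) and 0.00384 (complement and resting fibroblasts). Postn, which encodes the matricellular protein periostin (chromosome 3, 54359267 to 54391041 in GRCm38), rose from 970.2 ± 275 CPM in sham to 9675 ± 1960 CPM in TAC (SD, n = 3 each). Thbs4, a thrombospondin (chromosome 13, 92751586 to 92794818), rose from 34.6 ± 6.84 to 1240.3 ± 152 CPM, and Mki67, a marker of cycling cells, from 28.9 ± 21.8 to 238.7 ± 19.7 CPM. Gsn, which encodes gelsolin, fell from 3843 ± 485 to 984.9 ± 258 CPM. Of 12612 genes tested with edgeR, 2353 were past the threshold, 1044 higher and 1309 lower in TAC. Of these, 419 were higher and 539 lower by at least 1 on the log2 scale. The balance depended on the settings, with 1240 higher and 1139 lower under upper quartile scaling and 1579 higher and 1307 lower with no low-count filter. Among the tested genes, 36.2% had no overlap between the groups, against 10% by chance. Without sham replicate 2 the count was 1454, with 571 higher, and without sham replicate 3, 683 were higher.

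**Figure D1:**
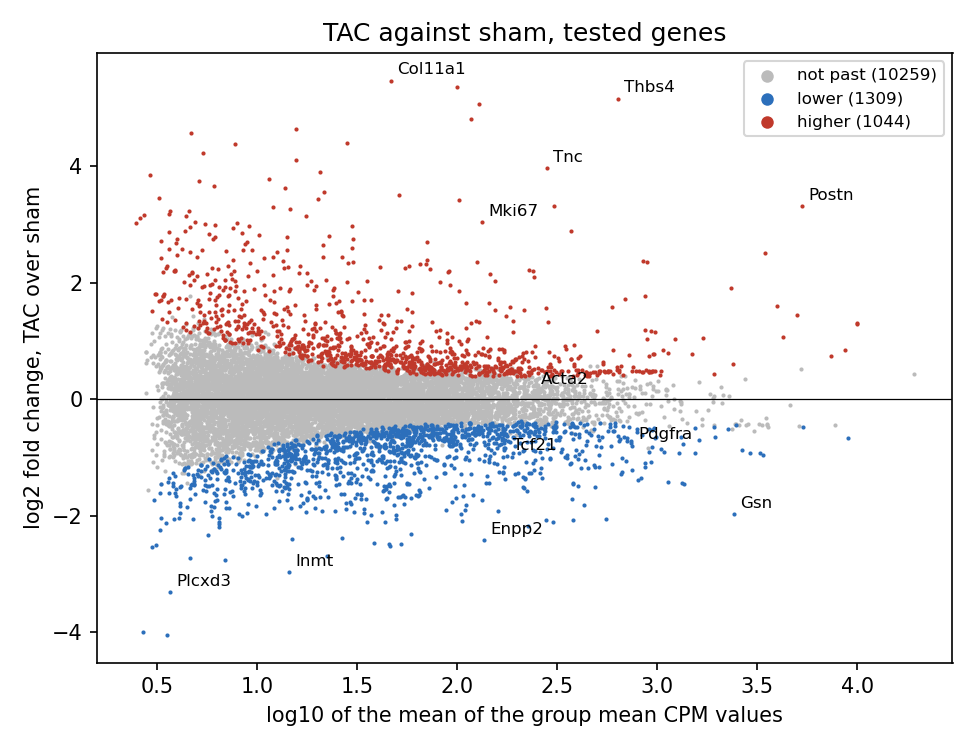
Each point is 1 tested gene, with the log10 of the mean of the group mean CPM values on the x axis and the log2 fold change, TAC over sham, on the y axis. The 1044 genes called higher are red, the 1309 called lower are blue and the others grey.

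The largest rises were in Col11a1, a fibrillar collagen chain, C1qtnf3, Thbs4, Ddah1, Cthrc1, Scube2, Cemip (listed as 9930013L23Rik), Frem1, Ckap2l, Ect2, H19 and Tnc. Col11a1 (chromosome 3, 114030479 to 114220756) had a log2 fold change of 5.47 ± 0.25 (SE) with an edgeR adjusted p of 8.47e-10, from 2.02 ± 0.0463 CPM to 91.2 ± 10.2 CPM (SD, n = 3). Its sham value rests on 4 counts in each library. Scube2, Cemip, Frem1, Ckap2l, Ect2 and H19 had at most 6 counts in any sham library. Cthrc1 had 40, 1 and 7 counts in sham replicates 1, 2 and 3. The fold changes of these genes are therefore imprecise. Tnc, which encodes tenascin C, had a log2 fold change of 3.97 ± 0.20 (SE), and H19, an imprinted noncoding RNA, one of 4.11 ± 0.36. The largest falls were in Plcxd3, Inmt, Il2ra, Ppm1l, Ces3, Tchh, Rasl11a, Tmprss2, Galnt15 (listed as Galntl2), Ppl, Slco2b1 and Enpp2. Plcxd3 had a log2 fold change of -3.31 ± 0.57 and Enpp2, the enzyme autotaxin, one of -2.42 ± 0.18, from 230.0 ± 30.7 to 42.7 ± 11.4 CPM. Plcxd3, Il2ra, Ppm1l, Tchh and Tmprss2 had at most 9 counts in any TAC library, so their falls are imprecise. Ces3 belongs to a carboxylesterase family, and its counts are uncertain to the extent that family members share reads.

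Many collagen and fibrillar matrix genes rose. Of 28 tested members of the list of collagens and fibrillar matrix, 20 rose and 2 fell, and 21 and 2 when adjusted over the list alone. The camera adjusted p was 1.02e-11, and the adjusted p = 0.0674 with an estimated correlation. Col1a1 rose by 1.61 ± 0.25 (SE) on the log2 scale, Col1a2 by 1.45 ± 0.19, Col3a1 by 1.29 ± 0.24, Col12a1 by 2.89 ± 0.17 and Fn1, fibronectin, by 2.51 ± 0.20. The members that fell were Emilin2 and Fbln1. Of 27 tested genes for collagen processing and crosslinking, 18 rose and 1, Pcolce2, fell, and 21 and 1 when adjusted over the list alone (camera adjusted p of 1.28e-08, and adjusted p = 0.0458 with an estimated correlation). They included the crosslinking enzyme Lox at 2.36 ± 0.17, Loxl3 at 1.66 ± 0.14, Plod2 at 1.33 ± 0.15 and the collagen chaperone Serpinh1 at 1.18 ± 0.16. Of 25 matricellular genes, 15 rose and 3 fell, with the same counts when adjusted over the list alone (camera adjusted p of 2.44e-08, and adjusted p = 0.0458 with an estimated correlation). Besides Thbs4, Tnc and Postn they included Ccn4 (listed as Wisp1) at 3.50 ± 0.21 and Ctgf at 1.77 ± 0.26, while Smoc2, Sparcl1 and Tgfbi fell.

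**Figure D2:**
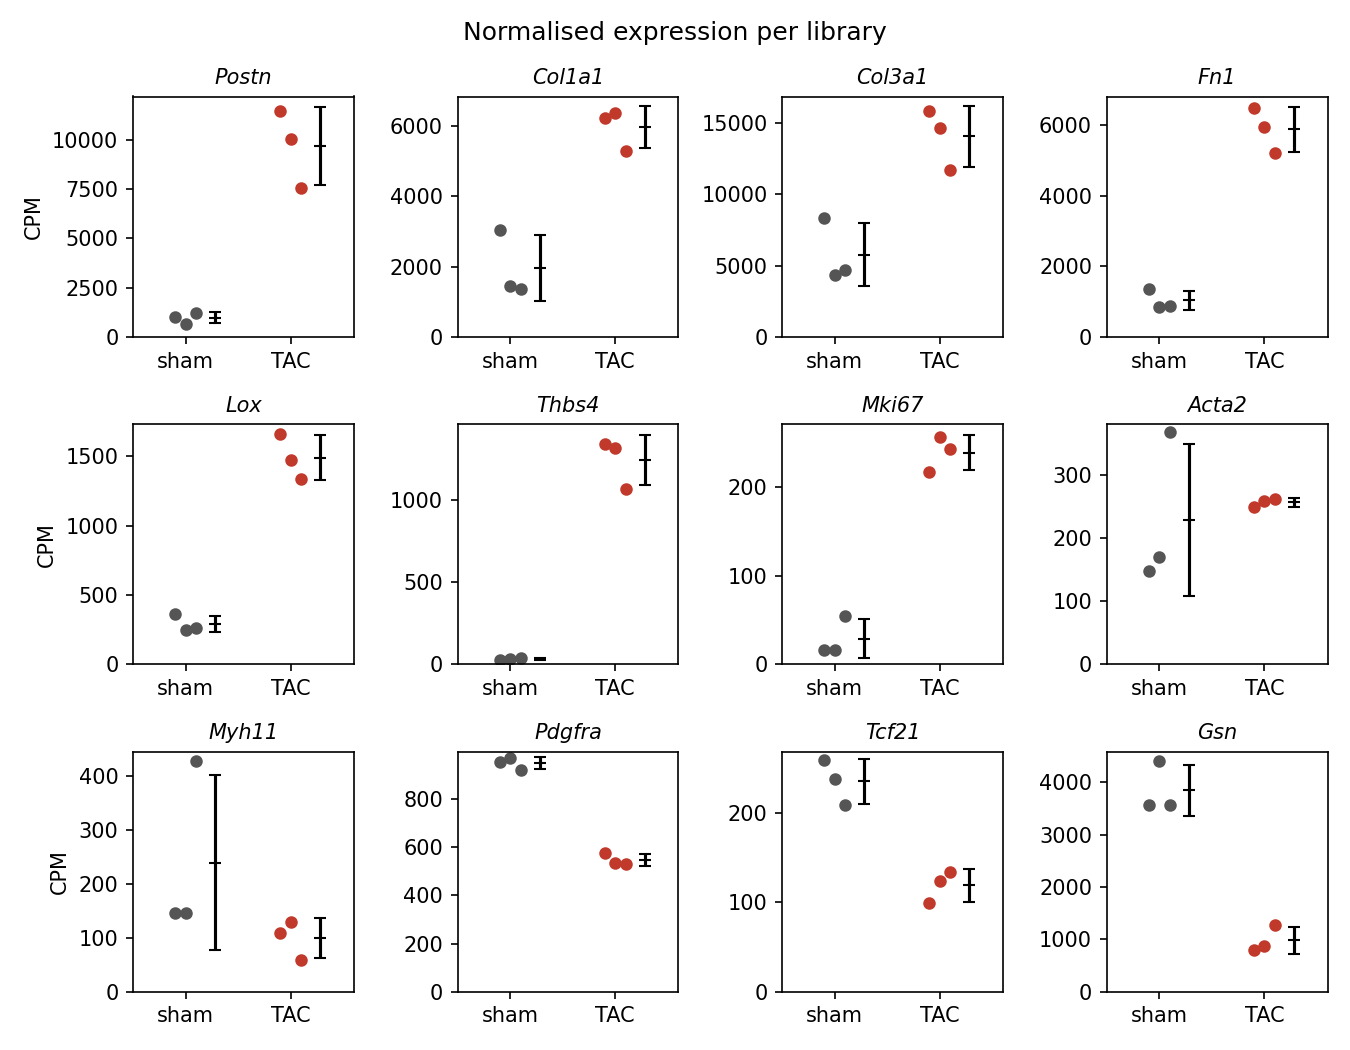
Each panel shows 1 gene, with CPM on the y axis and 1 point per library for sham and TAC, and the bar gives the mean and SD of the 3 libraries. Postn lies at a mean of 970.2 CPM in sham and 9675 in TAC, and sham replicate 3 has the highest value of both Acta2 and Myh11.

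Genes of mitosis rose nearly throughout their list. Of 37 tested genes of G2 and M phase, 36 rose and none fell, and the exception was Dlg7. The median log2 fold change was 2.53, with a camera adjusted p of 1.75e-25, and adjusted p = 0.107 with an estimated correlation; 36 rose when adjusted over the list alone. Mki67 rose by 3.04 ± 0.30 (SE), Anln by 2.98 ± 0.25, Hmmr by 3.27 ± 0.31 and Cenpf by 2.36 ± 0.20. Mki67 was at 16.0, 16.6 and 54.1 CPM in sham replicates 1, 2 and 3, and without replicate 3 its log2 fold change was 3.86. Leaving out its highest sham library raises this value by construction. Genes of S phase and DNA replication were not called as a list (4 rose and 2 fell of 20, 5 and 3 when adjusted over the list alone, camera adjusted p of 0.0570). Their median log2 fold change was 0.748, with 20 of 35 listed genes tested (camera adjusted p = 0.643 with an estimated correlation, fry adjusted p of 0.0901). Pole rose by 2.44 ± 0.44 and Tyms, Mcm6 and Hells rose as well, while Slbp fell and Rrm1 fell, the last with a log2 fold change of -0.98 ± 0.17. The sham value of Pole rests on 2, 2 and 5 counts in replicates 1, 2 and 3, so its fold change is imprecise. Ccnd1, cyclin D1, had 187.5 ± 23.2 CPM in sham and 172.0 ± 17.9 in TAC and did not pass (edgeR adjusted p of 0.58).

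Genes of resting fibroblasts and complement moved the other way. Of 32 tested, 23 fell and 1, Cfb, rose, and 25 and 1 when adjusted over the list alone (camera adjusted p of 1.02e-11, and adjusted p = 0.125 with an estimated correlation). Scara5 had a log2 fold change of -2.06 ± 0.16 (SE), Efemp1 of -1.89 ± 0.16, Gsn of -1.96 ± 0.19 and Fmo2 of -1.65 ± 0.17. Summed markers of pericytes, of epicardial and mesothelial cells and of Schwann cells were lower in TAC as well, at 0.541, 0.580 and 0.609 times sham, as were 17 of 34 immediate early and heat shock genes. C3 is in both the resting-fibroblast and complement list and the epicardial one. It made up 3456 of the 4218 CPM of the epicardial sum in sham and 1882 of 2445 CPM in TAC. Most of the fall of that sum is therefore the fall of C3. Among the study genes, Pdgfra fell with a log2 fold change of -0.80 ± 0.13 (SE), Ddr2 with -0.78 ± 0.14 and Tcf21 with -0.98 ± 0.15. The list of fibroblast markers held 6 rises and 6 falls of 16, 7 and 6 when adjusted over the list alone, and was not called (camera adjusted p of 0.766). Thy1, the sorting marker, had 133.6 ± 10.8 CPM in sham and 177.6 ± 27.6 in TAC (SD, n = 3), with an edgeR adjusted p of 0.060. Of the developmental transcription factors, Tbx20 was at 537.0 ± 74.7 and 608.4 ± 109 CPM and Gata4 at 87.4 ± 7.27 and 94.9 ± 10.6 CPM in sham and TAC, neither past the threshold, and Tbx18, Wt1 and Hand2 did not pass either. Pax3 was too low to test. Runx1 rose by 2.32 ± 0.18 and Meox1 by 2.20 ± 0.18, but the list of 36 cardiogenic and lineage factors was not called (5 rose and 6 fell, 7 and 8 when adjusted over the list alone, camera adjusted p of 0.900).

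Contractile genes gave a mixed picture. Acta2, smooth muscle actin and a usual marker of myofibroblasts, was at 229.2 ± 121 CPM in sham and 257.0 ± 6.52 in TAC, with a log2 fold change of 0.16 ± 0.24 (SE) and an edgeR adjusted p of 0.675. Sham replicate 3 had 369 CPM and the other sham libraries 149 and 170 CPM. Without it the log2 fold change was 0.68, with an adjusted p of 0.00769, a rise that leaving out the highest sham library gives by construction. Across all alternatives the adjusted p ranged from 0.00333 to 0.977. Of 29 tested genes of the contractile apparatus 9 rose and 3 fell, and 11 and 4 when adjusted over the list alone (camera adjusted p of 0.0301, and adjusted p = 0.700 with an estimated correlation). Actn1 rose by 1.97 ± 0.15, Palld by 2.34 ± 0.24, Myh9 by 0.82 ± 0.14 and Tagln by 0.74 ± 0.22, while Tpm3, Myh11 and Synpo2 fell. Myh11 was at 146, 146 and 427 CPM in sham replicates 1, 2 and 3, and without replicate 3 it did not pass (log2 fold change of -0.55, edgeR adjusted p of 0.139).

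Other lists moved by less or in both directions. Of 28 genes of endoplasmic reticulum folding, 8 rose and 1 fell, 9 and 2 when adjusted over the list alone (camera adjusted p of 0.00925, and adjusted p = 0.669 with an estimated correlation), Creb3l2 by 0.75 ± 0.14 and Pdia6 by 0.73 ± 0.15 (SE). Of 42 genes of oxidative phosphorylation only Atp5e rose (camera adjusted p of 0.0353, and adjusted p = 0.700 with an estimated correlation), and none passed when adjusted over the list alone. Leaving out 1 library gave this list a camera adjusted p from 0.00146 to 0.379, past the threshold no longer without sham replicate 1 or TAC replicate 3. Of 43 ribosomal protein genes, 6 rose, 5 when adjusted over the list alone (camera adjusted p of 3.13e-05, and adjusted p = 0.700 with an estimated correlation), among them Rps9 by 0.52 ± 0.15. Both of these lists lost their call when a trend of fold change with gene length was removed. Of 15 genes of angiotensin, endothelin and natriuretic signalling, 4 fell and 2, Nppa and Edn1, rose, 5 and 2 when adjusted over the list alone (camera adjusted p of 0.0353, and adjusted p = 0.302 with an estimated correlation). Nppa is also the only cardiomyocyte marker that rose. The sham value of Edn1 rests on 6, 6 and 2 counts in replicates 1, 2 and 3, so its fold change is imprecise. Of 34 immediate early and heat shock genes, whose RNA is sensitive to cell handling, 17 fell and 4 rose, 21 and 5 when adjusted over the list alone (camera adjusted p of 5.30e-05, and adjusted p = 0.125 with an estimated correlation), Atf3 with -1.49 ± 0.16 and Zfp36 with -0.91 ± 0.15. Not called as lists, with camera adjusted p from 0.397 to 0.753, were TGF-beta and BMP signalling (6 rose and 8 fell of 36), proteoglycans (6 and 5 of 20), matrix proteases and inhibitors (7 and 4 of 24) and growth factors and receptors (11 and 8 of 34). The same held for interferon response (5 rose and 10 fell of 27), cytokines and chemokines (4 and 4 of 24), the Wnt pathway (6 and 2 of 24), glycolysis (4 and 5 of 22) and lipid genes (0 and 3 of 26). Adjusted over each list alone, the rises and falls in these lists were 7 and 8, 6 and 5, 8 and 5, 11 and 9, 5 and 10, 4 and 5, 6 and 3, 5 and 5, and 0 and 3, in the order named. Within them Ltbp2 rose by 3.31 ± 0.19, Fmod by 2.21 ± 0.16, Timp1 by 1.53 ± 0.18, Frzb by 1.87 ± 0.14 and Cx3cl1 by 2.60 ± 0.23, and Irgm1 (listed as Irgm) fell, with -1.69 ± 0.18. Other falls in them were Adamts5 with -1.22 ± 0.14, Bmp2 with -1.49 ± 0.17, Tgfbr3 with -1.18 ± 0.16, Ccl11 with -1.82 ± 0.28 and Slc16a1 with -1.23 ± 0.19.

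**Figure D3:**
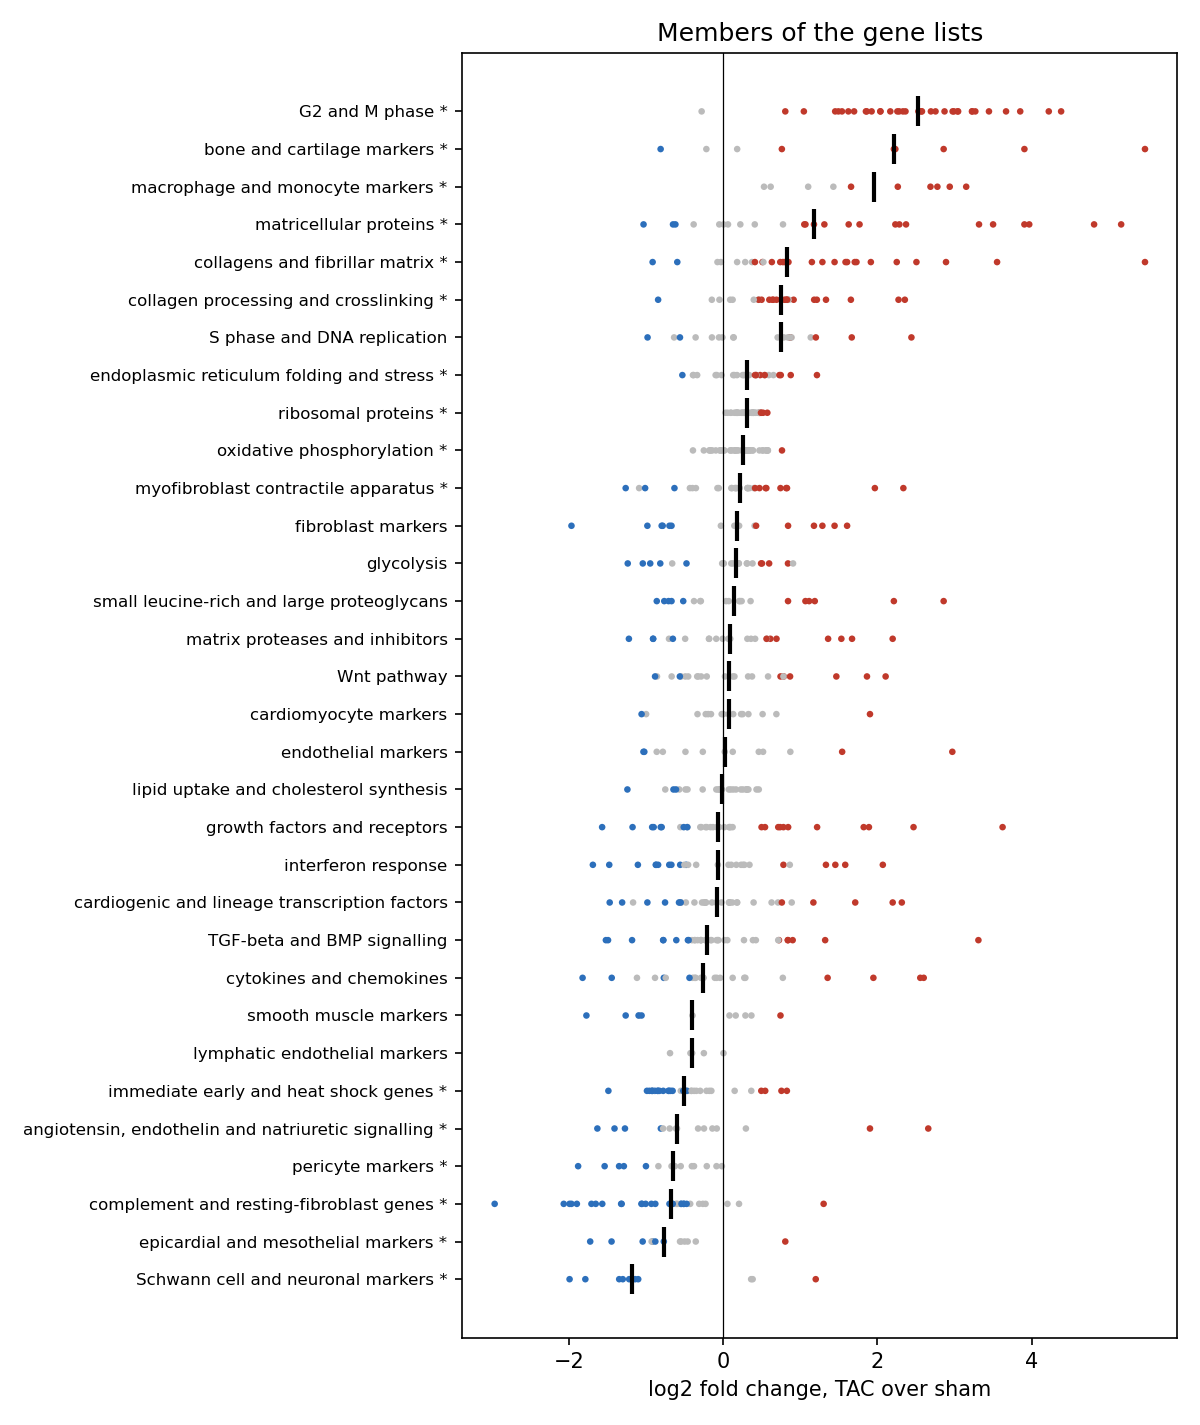
Each row is 1 of the 32 tested lists, each point a tested member at its log2 fold change (TAC over sham, x axis), red where called higher, blue where called lower and grey otherwise; the bar is the median and a star marks a camera adjusted p under 0.05 with the preset correlation. The median of the G2 and M phase list lies at 2.53.

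Markers of other cell types also differed between the libraries. Markers of macrophages summed to 110, 109 and 330 CPM in TAC replicates 1, 2 and 3 and to 89.1, 25.4 and 30.3 CPM in sham. Of 10 tested, 6 rose, with the same count when adjusted over the list alone (camera adjusted p of 0.000591, and adjusted p = 0.640 with an estimated correlation), and the list was not called without TAC replicate 3 (adjusted p of 0.127). Ptprc, the leukocyte antigen CD45, had 0 counts in the sham libraries, where 3 counts would be up to 1.57 CPM in a single library, and 3.12 ± 1.73 CPM in TAC. The class II gene H2-Aa rose by 2.13 ± 0.50 and Cd74, which encodes the invariant chain, by 1.65 ± 0.50 (SE). For H2-Aa, how reads shared by class II genes were counted is not given in the sources used here. H2-Aa and Cd74 were highest in TAC replicate 3, at 36.7 and 70.4 CPM, and Cd74 overlapped between the groups. Without that library the log2 fold changes were 1.32 and 0.86, and Cd74 did not pass (edgeR adjusted p of 0.168). Pericyte markers summed to 3956 ± 951 CPM in sham and 2140 ± 740 in TAC (SD, n = 3; exact permutation p = 0.1, the smallest possible), and 5 of 14 fell, 7 when adjusted over the list alone (camera adjusted p of 0.000405, and adjusted p = 0.643 with an estimated correlation), Kcnj8 with -1.29 ± 0.17 (SE). The sums were 3536, 3287 and 5045 CPM in sham replicates 1, 2 and 3. In TAC replicates 1, 2 and 3 they were 2732, 2378 and 1311 CPM. Abcc9 alone went from a mean of 1193 CPM in sham to 469 CPM in TAC. Of 10 Schwann cell and neuronal markers 7 fell and Ncam1 rose, unchanged when adjusted over the list alone (camera adjusted p of 0.00814, and adjusted p = 0.150 with an estimated correlation). Of 13 epicardial and mesothelial markers 6 fell and Aldh1a2 rose, unchanged when adjusted over the list alone (camera adjusted p of 0.00160, and adjusted p = 0.511 with an estimated correlation), Muc16 with -1.72 ± 0.24. Of 9 bone and cartilage markers 6 rose and Akp2 fell, unchanged when adjusted over the list alone (camera adjusted p of 5.30e-05, and adjusted p = 0.0845 with an estimated correlation), Spp1 by 3.91 ± 0.47. Spp1, Col11a1, Fmod, Comp and Acan also stand in the matrix lists, so most of these rises are shared with them. Smooth muscle (1 rose and 4 fell of 11), endothelial (2 and 2 of 13), cardiomyocyte (1 and 1 of 17) and lymphatic (none of 5) markers were not called. Adjusted over the list alone their rises and falls were 2 and 4, 3 and 3, 1 and 1, and 0 and 0. Among endothelial markers Erg rose by 2.97 ± 0.38 and Ptprb by 1.54 ± 0.19, Tek fell, with -1.03 ± 0.13, as did Esam1, and Pecam1 did not pass. The sham value of Erg rests on 3, 2 and 7 counts in replicates 1, 2 and 3, so its fold change is imprecise and depends on replicate 3. Lymphocyte (2 rose of 2, H2-Aa and Cd74), neutrophil (0 of 1), adipocyte (1 fell of 3) and erythroid (0 tested) lists had under 5 tested members and no list test. The other lymphocyte markers were not tested.

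**Figure D4:**
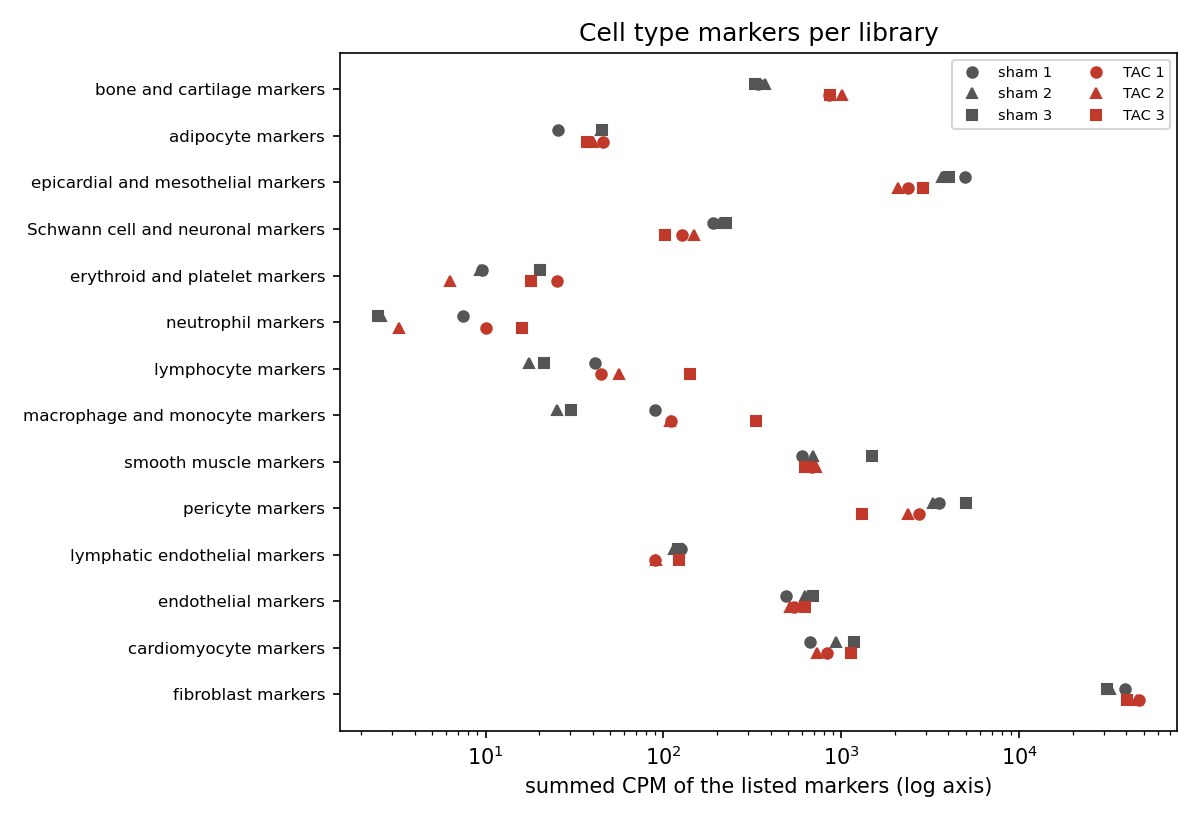
Summed CPM of each cell type list (x axis, log scale) per library, grey for sham and red for TAC, with the replicate shown by the symbol. TAC replicate 3 has the highest macrophage sum, at 330 CPM, and sham replicate 3 the highest smooth muscle sum, at 1479 CPM.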

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

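The thinning and length tests of the gene counts and the smooth muscle test were chosen after their results had been seen; the background test and the splits were written down before. Removing the length trend was chosen after seeing the data, and its tests on single lists were written down after its effect on the gene counts was seen but before any list value with it. The reports' headers, which no comparison uses, give the matched reads of each library. The share of these counted on gene rows was 40.3 ± 2.53% in TAC and 30.1 ± 4.40% in sham (SD, n = 3; two-sided exact permutation p = 0.1, the smallest possible), higher in every TAC library than in every sham library. This share cannot be told apart from the operation, since it follows the groups.

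The first pattern weighed was the 2353 called genes. Differences in depth and gene length do not account for most of it: with every library thinned to the smallest, 2129 genes were called, and with the length trend removed 1778 of the 2353 were still called. Counts on 68 olfactory receptor genes were taken as a stand-in for reads from genomic DNA. Their excess in sham would cover 12.2% of the median lower gene's drop. By the limits written down before, this value decided neither way. At least 50% of the drop was covered for 86 of the 1309 lower genes. Of the olfactory counts, 95.8% fell on Olfr1033, Olfr558 and Olfr78, where reads spread over genes would not gather. The 12.2% therefore rests mostly on these genes, and the excess over the other olfactory genes was not computed. The gathering of counts argues against spread reads as the source of most olfactory counts. In sham a lower share of matched reads was counted on genes, which this test did not weigh. Genomic DNA as a cause of the falls stays open. Of the 10 splits of the 6 samples, 1, the real one, gave as many genes, the highest other giving 0, and with 10 splits the share is never under 0.1. Every other split has TAC and sham libraries on each side, which widens the spread within a side. The 0 therefore does not show what chance alone would give. A response to TAC stays open, and what the share of reads counted on genes contributes was not tested.

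The second pattern was the number of called lists. The real split called 16 lists and the highest other split called 13, none of the other splits called a gene, and with 10 splits the share is never under 0.1. The other splits hold TAC and sham libraries on each side in unequal numbers, so part of the difference between the groups remains in them. The lists called there may reflect that part, so these counts cannot show how many lists chance alone would call. With camera's correlation estimated, 2 lists were higher and 0 lower. The number of lists called with a preset correlation is therefore weak evidence in these libraries. Across genes, which are not independent, the log2 fold change correlated with log gene length at a Spearman rho of -0.29. With that trend removed, the camera adjusted p was 0.977 for oxidative phosphorylation, with its direction reversed, and 0.233 for ribosomal proteins, so gene length is a candidate explanation of both calls.

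The third pattern was the absence of a call for Acta2. The other 12 smooth muscle markers had a median level in sham replicate 3 of 1.96 times the mean of the other sham libraries, and 9 of them at least 1.5 times. Smooth muscle or pericyte RNA in that library may have hidden a rise of Acta2. Without sham replicate 3 the log2 fold change was 0.68, but leaving out the sham library with the highest Acta2 raises it by construction. A difference in activation between the libraries stays open and untested.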

How the results depend on the processing

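The settings that thin the libraries, remove length or GC trends, or leave out numbered loci or both libraries numbered 3 were chosen after seeing the data; the length tests of 2 single lists were written down before their own values were seen. The count of called genes ranged from 1454 (without sham replicate 2) to 2261 (without TAC replicate 1) over the settings that leave out 1 library, genes higher from 571 to 997 and genes lower from 883 to 1264; these fits have fewer samples. Genes higher numbered 1579 and lower 1307 with no low-count filter, where more genes were tested, and 1240 and 1139 with upper quartile factors, so more genes were higher than lower there. At an adjusted p under 0.01 the counts were 1159, 479 higher and 680 lower, and with a change of at least 1 on the log2 scale 958, 419 and 539, by construction. DESeq2 called 1898 genes, of which 1885 were among the 2353. Without both libraries numbered 3, 1792 genes were called. With camera's correlation estimated, 2 lists were higher and 0 lower, and with fry 5 were higher and 4 lower. The cause was not tested.

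Same-numbered libraries had correlations of deviations of 0.08, 0.03 and -0.09, and differently numbered libraries of the 2 groups had -0.11 to 0.08. Sham replicates 1, 2 and 3 correlated best with TAC replicates 1, 3 and 2. These values show no pairing by number, but so few libraries cannot exclude one. With a replicate block 2346 genes were called, 1029 higher and 1317 lower, and 11 lists higher and 6 lower.

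Of the called genes, at most 2 changed sign in any setting. Among named genes and lists, sign changes fell on those not past the threshold, with the exception of oxidative phosphorylation (adjusted p of 0.977 with the length trend removed). Leaving out 1 library moved Acta2 from -0.0750 (without sham replicate 1) to 0.683 (without sham replicate 3), with -0.0167 without sham replicate 2. Flt4 ranged from -0.753 to 0.105, and Tbx18 was at 0.0484 and Hand2 at 0.0930 without both libraries numbered 3. The list of lineage factors turned, with adjusted p of 0.879 (fry), 0.922 (no filter), 0.766 (mean CPM of at least 5), 0.990 (replicate block), 0.937, 0.928, 0.920 and 0.507 (without sham replicates 2 and 3 and TAC replicates 1 and 3), 0.537 (without both libraries numbered 3), 0.897 (thinned), 0.903 (length) and 0.944 (no numbered loci). Cardiomyocyte markers turned at 0.948 (shared members left out), 0.157 and 0.127 (without sham replicate 1 and TAC replicate 3), 0.717 (without both libraries numbered 3), 0.923 (length) and 0.947 (GC), and leaving out 1 library gave 0.127 to 0.911; smooth muscle markers at 0.885 (without sham replicate 3; lowest 0.112) and 0.717 (without both libraries numbered 3); growth factors at 0.965 (without TAC replicate 1; lowest 0.350), lipid genes at 0.941 (without TAC replicate 2) and endothelial markers at 0.976 (without TAC replicate 3), though they were called without sham replicate 3 (0.0186). The cause was not tested. Counts on genes were lower in sham, which limits what can be seen of low genes there.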

Other observations

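Of 6 gene sets put together after values had been seen, 2 are described here, whose called genes are in no list. Among imprinted genes, H19 rose with a log2 fold change of 4.11 ± 0.36 (SE; edgeR adjusted p of 9.23e-07), while Igf2, its neighbour, was at 39.6 ± 1.63 CPM in sham and 39.9 ± 9.33 CPM in TAC (SD, n = 3). The sham value of H19 rests on 5, 2 and 3 counts in replicates 1, 2 and 3. Mest rose by 2.18 ± 0.23, Cdkn1c fell, with -1.11 ± 0.23, and Peg10 with -1.03 ± 0.17; 7 of the 11 tested did not pass. Of 13 glutathione transferase genes, 4 fell and none rose. Gstm1 had a log2 fold change of -2.06 ± 0.14, Gstm3 of -2.05 ± 0.19 and Gsta3 of -1.87 ± 0.27. These genes are similar in sequence, and how reads shared between them were counted is not given in the sources used here.

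The other sets looked at were tendon genes (3 rose and 1 fell of 5 tested), which the fixed lists mostly hold already, kinesins (7 and 2 of 22), aldehyde dehydrogenases (1 and 3 of 11) and solute carriers (9 and 26 of 159).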
